A study of Mus musculus with 6 samples.

How the data were processed

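The series holds single-cell RNA sequencing of ascites from 6 C57BL/6 mice that had been injected with ID8 mouse ovarian surface epithelial cells. Per the labels, 3 mice received Trp53-/- cells (Trp53_KO) and 3 received Trp53+/+ cells (Trp53_WT). Red blood cells were lysed and live cells were sorted with a CD45 stain before droplet capture, per the labels' protocols, which do not state how the CD45 gate was used. For each mouse the authors deposited raw UMI counts per gene and barcode, made with Cell Ranger 6.0.0 per the file headers and aligned to mm10 per the labels. Seurat is named in the submitters' processing notes without a version. The authors also deposited a cluster number (20 clusters) and a predicted cell type label for each cell they kept, in files whose headers name the columns but no reference. Their marker tables give a natural log fold change between sets of cells and a p-value, per the file headers, with single cells as replicates and no comparison of the genotypes.

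Cells were those in the authors' tables, 24707 of 25648 deposited barcodes. Of the 941 left out, 910 had at least 20% mitochondrial UMIs. Kept cells had at least 500 UMIs and at most 19.9% mitochondrial UMIs. UMIs in kept cells ranged from 13495447 to 37993464 per library. Intervals and floors cover counting error only, and a floor is 3 counts of the total.

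Cell classes were the authors' labels pooled to major classes. The alternative class was the majority label of each deposited cluster. UMI counts were summed per mouse and class, so that mice and not cells were the replicates, and 5 classes had at least 20 cells in enough libraries. Trp53_KO was compared with Trp53_WT by edgeR 4.0.16 (R 4.3.3, TMM scaling, default expression filter, robust quasi-likelihood test) with Benjamini-Hochberg adjustment within a class and a threshold of 0.05. No replicate block was fitted in the main tests, since no label says that mice with the same replicate number share a litter or day. Gene lists (25) were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over 120 class-by-list tests of at least 5 members. Camera with an estimated correlation and fry were alternatives. Some lists share members. Zbp1, Ifi204 and Irf7 are among those in both the type I interferon and the nucleic acid sensing lists. Tap1 and Psmb8 are among those in both the interferon gamma and the MHC class I lists. Class shares per mouse were compared by edgeR on cell numbers and by a two-sided exact permutation test, whose smallest p is 0.1 for 3 against 3 mice. The difference of the change between macrophages and T cells was tested with limma on the difference of log2 CPM within each mouse. The authors' 14 marker comparisons were set against the same contrasts in counts summed per library. Python 3.11.15 with scanpy 1.11.5 served for reading and for doublet scores.

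Named genes followed a rule. In each class these were up to 8 genes per direction with the largest fold change among those past the threshold, with an average log2 CPM of at least 5 and no overlap between the groups. Where none passed, the 2 smallest p per direction were taken as values only. To these came the 4 members with the smallest p of each list past the threshold and a few genes of interest such as Isg15, Cd274 and Cdkn1a. The lists, the main tests, this rule and the alternatives not said to be added later were fixed before the data were examined. Positions are from GENCODE vM21 on mm10.

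Alternatives were DESeq2 1.42.0, other scalings, no or a stricter count filter, the replicate block, leaving out each mouse, stricter cell filters, classes from clusters, summed counts thinned to the smallest library of the class, and removal of called doublets. A separate check of depth on the level of a list thinned each cell to 1000 UMIs. Scrublet called 102 cells (0.413%), too few for this number of cells, so removal of the 4% with the highest score in each library was added after the data were seen. Each test was run on simulated counts, with genes drawn independently. These had 200 changed genes for the tests of genes and of the difference between classes, 1 list changed 2-fold for camera, and 1 class lowered 8-fold for shares. Of genes changed 4-fold, edgeR recovered 75.4% in macrophages and monocytes, 92.1% in neutrophils, 98.2% in dendritic cells, 98.3% in T cells and 88.5% in B cells. Calls on unchanged genes were 18 of 148 calls in macrophages and monocytes, 9 of 151 in neutrophils, 17 of 155 in dendritic cells, 20 of 176 in T cells and 13 of 139 in B cells, above the nominal rate in each. DESeq2 made 54 such calls among 205 in macrophages and monocytes. Camera recovered the changed list in each class, and outside the interferon and sensing lists it also called 2 unchanged lists in macrophages and monocytes, 2 in B cells and 0 in the other classes. The test of shares recovered the class in 100 of 100 simulations, with 10 calls on unchanged classes. The spread between mice was preset there and not taken from the data, so these counts need not hold for the real shares. Natural killer cells and epithelial or stromal cells had too few cells for a test of genes. Plot coordinates and shortened marker tables were not used.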

Results

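Ascites cells of 6 mice were profiled by droplet single-cell RNA sequencing. ID8, a line of mouse ovarian surface epithelial cells, had been injected into the peritoneal cavity either without Trp53 (Trp53_KO, n = 3 mice) or with it (Trp53_WT, n = 3 mice). The host mice were of 1 strain, so the comparison asks how loss of p53 in the injected cells goes with the state of the immune cells around them. The kept cells numbered 4589, 3968 and 3535 in the Trp53_KO libraries and 3712, 4506 and 4397 in the Trp53_WT libraries. Total UMIs were 34551049, 37993464 and 23979650 in Trp53_KO and 13495447, 23650644 and 17994367 in Trp53_WT. Median UMIs per cell were 3226, 9046.5 and 3538 against 1932, 2864.5 and 1719, so over all cells depth was higher in each Trp53_KO library than in any Trp53_WT library. Within macrophages and monocytes the medians overlapped, at 13789.5, 9584 and 12542 against 12065.5, 4867 and 11450. They also overlapped within T cells and neutrophils, but not within dendritic cells and B cells. Values below are means ± SD over 3 mice per group in CPM, the summed UMIs of a class scaled to a fixed total, unless stated. The CPM of single genes other than Trp53 are after TMM scaling, and those of Trp53 and of sums of markers are not.

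Trp53, the gene deleted in the injected cells, was read in the few epithelial or stromal cells of each library. It stood at 7.61, 15.0 and 14.9 CPM in Trp53_KO replicates 1 to 3, from 4, 29 and 15 UMIs in 14, 37 and 22 cells. In Trp53_WT it stood at 61.8 CPM in replicate 2 (24 UMIs, 23 cells, exact 95% interval 39.6 to 92.0) and at 121 CPM in replicate 3 (5 UMIs, 1 cell, 39.3 to 283). Trp53_WT replicate 1 had 0 UMIs in 3 cells, which allows up to 153 CPM at 3 counts, and its exact 95% interval ended at 188 CPM. Those 3 cells held 0 UMIs of the epithelial genes Krt8, Krt18, Krt19 and Msln, so their label is doubtful. The group values were 12.5 ± 4.23 and 61.0 ± 60.6 CPM, a difference smaller than the spread in Trp53_WT with that library, and the class had too few cells for a test. The intervals of Trp53_WT replicates 2 and 3 lay above those of all Trp53_KO libraries, which ended at 24.6 CPM or less. In host macrophages and monocytes Trp53 was alike in both groups, 30.4 ± 6.47 against 32.7 ± 4.54 CPM. The labels do not say which part of the gene was deleted.

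Macrophages and monocytes of the Trp53_KO mice carried more interferon-response RNA. All 55 measured members of the type I interferon list, genes that cells switch on against viruses, had a positive fold change, with a median log2 fold change of 1.04 (camera adjusted p = 3.74e-19; adjusted p = 0.666 with an estimated correlation). All 25 members of the interferon gamma list were positive as well (median 0.80, adjusted p = 4.61e-10; adjusted p = 0.632 with an estimated correlation). Irf7, a transcription factor that amplifies the interferon response, stood at 164 ± 97.1 against 16.8 ± 7.10 CPM, a log2 fold change of 3.27 (SE 0.66, edgeR adjusted p = 0.414). Irf7 is ENSMUSG00000025498, on chromosome 7 from 141262706 to 141266481. Rsad2, an antiviral enzyme, stood at 32.0 ± 21.9 against 3.12 ± 1.37 CPM, and Cd274, which encodes the checkpoint ligand PD-L1, at 31.4 ± 10.6 against 13.4 ± 5.10 CPM.

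Genes that present peptides to T cells moved the same way in macrophages and monocytes. Of 23 members of the MHC class I list, 21 were positive (median 0.50, adjusted p = 3.56e-08; adjusted p = 0.614 with an estimated correlation), and 10 rose when adjusted over the list alone against 0 over all genes tested. B2m, the shared light chain of class I, stood at 5228 ± 204 against 2396 ± 615 CPM, and H2-T22, a nonclassical class I gene, at 104 ± 30.7 against 41.6 ± 4.17 CPM. Adjusted over the list alone, 1 type I interferon gene and 8 interferon gamma genes rose, with 0 of either over all genes tested. Of 23 members of the nucleic acid sensing list, 18 were positive (median 0.33, adjusted p = 0.00163; adjusted p = 0.821 with an estimated correlation). That call was lost without Trp53_KO replicate 3 (adjusted p = 0.0793) and without Trp53_WT replicate 1 (adjusted p = 0.0721).

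Genes of alternatively activated macrophages fell as a list, with 15 of 20 members negative (median -0.70, adjusted p = 0.000490; adjusted p = 0.440 with an estimated correlation). Adjusted over the list alone, 3 fell, and 0 did over all genes tested. Cd163, the scavenger receptor for haemoglobin, stood at 28.1 ± 5.25 against 172 ± 70.9 CPM, a log2 fold change of -2.61 (SE 0.35, edgeR adjusted p = 0.379, DESeq2 adjusted p = 4.89e-11). Stab1, another scavenger receptor, stood at 72.1 ± 6.71 against 177 ± 35.5 CPM. Arg1, an arginine-degrading enzyme, overlapped between the groups, and its log2 fold change of -0.56 (SE 0.56) became 0.041 without Trp53_WT replicate 1. Of 32 oxidative phosphorylation genes 28 were negative, by a small amount (median -0.14, adjusted p = 0.000363; adjusted p = 0.703 with an estimated correlation). The neutrophil list did not pass by label (median -0.061, adjusted p = 0.0933), and with classes from clusters it fell (median -1.52, adjusted p = 5.86e-06; adjusted p = 0.772 with an estimated correlation). Red cell RNA moved with the groups in the same cells. All 7 erythroid genes were negative (adjusted p = 8.73e-07; adjusted p = 0.614 with an estimated correlation), and Hba-a1, a haemoglobin gene with a near-identical copy, stood at 124 ± 207 against 3281 ± 2707 CPM.

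Gene by gene, edgeR called 0 of 11466 genes in macrophages and monocytes, with 1144 at an unadjusted p under 0.05, while DESeq2 called 131, of which 72 were higher and 59 lower. The count was 8 without Trp53_KO replicate 2 and 1 without Trp53_WT replicate 1. The groups did not overlap for 17.0% of genes, where chance gives 10%. Here and below this 10% is an average over splits of the mice. Its spread over other splits was not computed, so a share above it is no test of the groups. The smallest p values in each direction belonged to Ddit3, a stress-response transcription factor (47.7 ± 8.38 against 16.1 ± 4.14 CPM), Arl5c, Bach2os and Adora2b, an adenosine receptor.

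**Figure D1:**
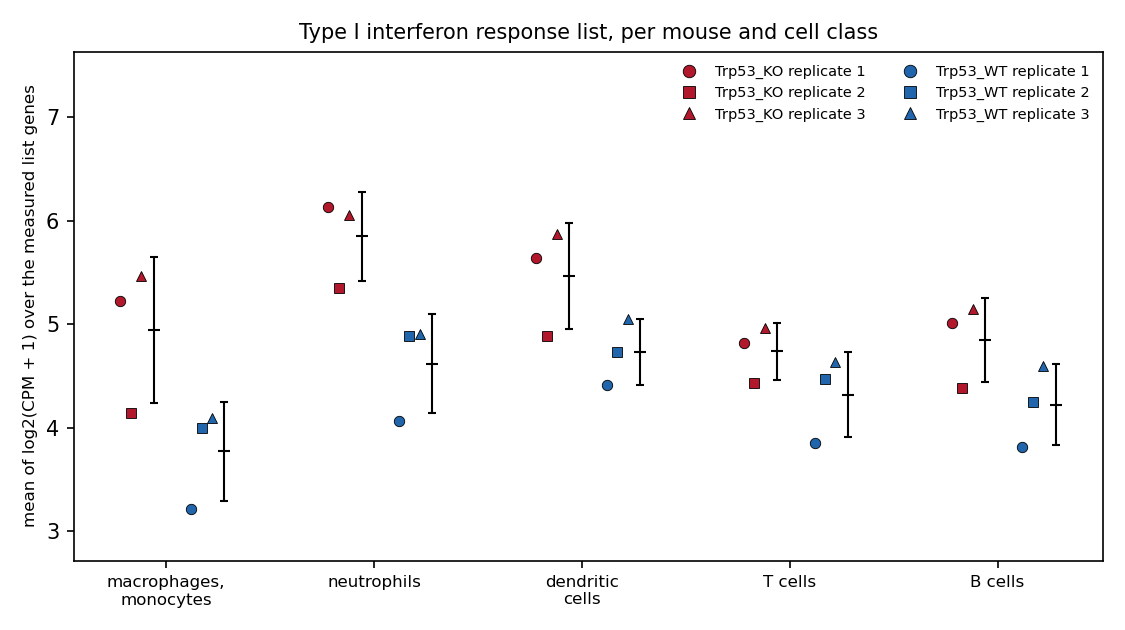
Mean log2(CPM + 1) of the type I interferon list in each mouse and cell class, with points for replicates and bars for the mean ± SD of 3 mice. In macrophages and monocytes the Trp53_KO mice lay at 5.22, 4.14 and 5.47 and the Trp53_WT mice at 3.21, 4.00 and 4.09.

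Neutrophils of the Trp53_KO mice had higher levels of 4 interferon-inducible genes that passed the test over all genes. Zbp1, a sensor of Z-form nucleic acid, rose from 12.9 ± 4.77 to 83.6 ± 35.7 CPM, a log2 fold change of 2.83 (SE 0.38, adjusted p = 0.0228). Ifi204, a DNA sensor of the interferon-inducible p200 family, rose from 14.8 ± 2.89 to 63.7 ± 19.1 CPM (log2 fold change 2.24, SE 0.28, adjusted p = 0.0149). Slfn4 and Slfn5, of the interferon-induced Schlafen family, rose from 36.9 ± 7.65 to 123 ± 30.5 CPM (adjusted p = 0.0182) and from 10.5 ± 3.83 to 51.3 ± 24.0 CPM (adjusted p = 0.0352). Zbp1 is ENSMUSG00000027514 on chromosome 2 (173206612 to 173218923) and Ifi204 is ENSMUSG00000073489 on chromosome 1 (173747293 to 173766943). Slfn4 is ENSMUSG00000000204 (83175186 to 83190216) and Slfn5 is ENSMUSG00000054404 (82951349 to 82964840), both on chromosome 11. The gene that fell was Hbb-bt, a haemoglobin chain with a near-identical copy, from 530 ± 203 to 0.472 ± 0.817 CPM (adjusted p = 0.000433).

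All 31 type I interferon genes measured in neutrophils were positive (median 0.88, adjusted p = 4.00e-16; adjusted p = 0.607 with an estimated correlation), and 17 rose when adjusted over the list alone against 3 over all genes tested. Of 13 nucleic acid sensing genes 10 were positive, with 4 risen adjusted over the list alone and 2 over all genes tested (median 0.46, adjusted p = 5.55e-05; adjusted p = 0.258 with an estimated correlation). Those 2 were Zbp1 and Ifi204, which also belong to the type I interferon list. All 19 MHC class I genes were positive, and 10 rose adjusted over the list alone (median 0.68, adjusted p = 8.73e-07; adjusted p = 0.607 with an estimated correlation). H2-K1, a classical class I chain, stood at 745 ± 111 against 335 ± 104 CPM. Mitochondrially encoded genes were higher in all 12 members, 8 of them risen adjusted over the list alone (median 1.00, adjusted p = 7.21e-09; adjusted p = 0.614 with an estimated correlation), with mt-Co1, a respiratory chain subunit, at 3746 ± 1242 against 1248 ± 361 CPM. Lipid and complement macrophage genes were positive in 14 of 14 members (median 0.51, adjusted p = 0.000769; adjusted p = 0.614 with an estimated correlation). Macrophage marker RNA in these neutrophils was 10160 ± 3831 against 7313 ± 1860 CPM, and RNA of red cell and platelet markers was 242 ± 66.7 against 7405 ± 3943 CPM. RNA of macrophages in the droplets was not separated from a change in neutrophils, for the single genes that rose or for these lists. All 5 erythroid genes were negative, with 4 fallen adjusted over the list alone and 1 over all genes tested (adjusted p = 1.53e-13; adjusted p = 0.258 with an estimated correlation).

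Several weaker lists in neutrophils did not hold under each left-out library. The MHC class II list (9 of 9 positive, adjusted p = 0.00667; adjusted p = 0.821 with an estimated correlation) gave adjusted p = 0.0729 without Trp53_KO replicate 3, 0.0653 without Trp53_WT replicate 1 and 0.286 without Trp53_WT replicate 3. The naive and memory T cell list (7 of 7 positive, adjusted p = 0.0112; adjusted p = 0.632 with an estimated correlation), gave 0.0577 and 0.0754 without Trp53_KO replicates 1 and 2, 0.0791 and 0.510 without Trp53_WT replicates 1 and 3, and 0.0653 with classes from clusters. The monocyte list (7 of 8 positive, adjusted p = 0.00333; adjusted p = 0.632 with an estimated correlation) gave 0.0769 without Trp53_KO replicate 3 and 0.222 with classes from clusters (median 0.43 against 0.96 by label). The neutrophil and granulocytic suppressor list (18 of 21 positive, adjusted p = 0.00851; adjusted p = 0.821 with an estimated correlation) includes Lcn2, an iron-sequestering granule protein, at 3840 ± 1283 against 1811 ± 24.8 CPM. It gave 0.180 without Trp53_KO replicate 3 and 0.165 and 0.0547 without Trp53_WT replicates 1 and 3, and it pointed down with classes from clusters (adjusted p = 0.252). Oxidative phosphorylation (24 of 32 negative, adjusted p = 0.0272; adjusted p = 0.682 with an estimated correlation) gave 0.0595, 0.0795 and 0.0769 without Trp53_KO replicates 1 to 3, and 0.0816 and 0.0838 without Trp53_WT replicates 1 and 3. With classes from clusters it gave 0.801, with a median of -0.031 against -0.16 by label.

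In total edgeR called 5 of 5400 genes in neutrophils, 4 higher and 1 lower, and 519 had an unadjusted p under 0.05. Without the robust option it called 7, of which 3 were higher and 4 lower. With the replicate block, a pairing that no label supports, it called 85, of which 77 were higher and 8 lower. DESeq2 called 54 and gave no adjusted p for the 4 genes that rose. The count was 0 without Trp53_KO replicate 1, 9 without replicate 2 and 1 without replicate 3. That 1 gene was lower, so the 4 genes that rose were lost without replicate 1 and without replicate 3. The count was 8, 13 and 10 without Trp53_WT replicates 1, 2 and 3. With classes from clusters it was 57, where Ifi204 (adjusted p = 0.0262) and Slfn5 (adjusted p = 0.0376) passed while Zbp1 (0.159) and Slfn4 (0.0819) did not. By cluster the count was 10, 53 and 6 without Trp53_KO replicates 1, 2 and 3, and 0, 151 and 4 without Trp53_WT replicates 1, 2 and 3. The 4 genes without Trp53_WT replicate 3 were all lower. The groups did not overlap for 16.1% of genes, where chance gives 10%.

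Dendritic cells of the Trp53_KO mice showed the interferon list higher in 36 of 40 members (median 0.66, adjusted p = 4.26e-12; adjusted p = 0.632 with an estimated correlation), 5 of which rose adjusted over the list alone and 0 over all genes tested. Irf7 stood at 52.1 ± 12.8 against 12.5 ± 3.08 CPM (log2 fold change 2.12, SE 0.31, adjusted p = 0.0750, and 0.0417 with classes from clusters). MHC class I genes were positive in 20 of 22 members, with 5 risen adjusted over the list alone (median 0.33, adjusted p = 4.49e-07; adjusted p = 0.258 with an estimated correlation), and H2-Q7, a class I gene with the close copy H2-Q6, stood at 142 ± 22.8 against 54.5 ± 13.2 CPM. Genes of the naive and memory T cell list were positive in 9 of 9 members (median 0.52, adjusted p = 0.00654; adjusted p = 0.510 with an estimated correlation). Neutrophil genes were lower in 4 of 5 members, each fallen adjusted over the list alone (median -3.25, adjusted p = 5.33e-05; adjusted p = 0.258 with an estimated correlation), among them S100a8, an abundant neutrophil protein, at 21.7 ± 4.36 against 303 ± 208 CPM. By cluster, 40.2, 44.9 and 33.3% of dendritic cells held a UMI of S100a8, S100a9 or Retnlg in Trp53_KO. In Trp53_WT it was 100, 55.4 and 81.9%. RNA of neutrophils in the droplets was not separated from a change in dendritic cells.

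Other lists in dendritic cells did not hold under each left-out library. Nucleic acid sensing (11 of 14 positive, adjusted p = 0.00395; adjusted p = 0.703 with an estimated correlation) gave 0.0826 without Trp53_KO replicate 1 and 0.0635 without Trp53_WT replicate 1. Interferon gamma genes (12 of 16 positive, adjusted p = 0.0343; adjusted p = 0.744 with an estimated correlation) gave 0.127 without Trp53_KO replicate 3, 0.0662 and 0.147 without Trp53_WT replicates 1 and 2, and 0.0711 with classes from clusters. MHC class II genes, which present peptides to helper T cells, were negative in 11 of 12 members (median -0.33, adjusted p = 0.0216; adjusted p = 0.821 with an estimated correlation), with 0.0895 and 0.0883 without Trp53_KO replicates 1 and 3 and 0.505 without Trp53_WT replicate 2. Proliferation genes (11 of 14 positive, adjusted p = 0.0130; adjusted p = 0.821 with an estimated correlation) gave 0.462 without Trp53_KO replicate 3, 0.0635 without Trp53_WT replicate 1 and 0.195 with classes from clusters. By edgeR 0 of 5973 genes passed, with 492 at an unadjusted p under 0.05, and DESeq2 called 13. The count was 5 without Trp53_KO replicate 2, and 4, 4 and 5 without Trp53_WT replicates 1, 2 and 3. The groups did not overlap for 13.7% of genes, where chance gives 10%.

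T cells of the Trp53_KO mice had type I interferon genes higher in 38 of 42 members, by less than in macrophages (median 0.38, adjusted p = 2.15e-07; adjusted p = 0.736 with an estimated correlation), with 3 risen adjusted over the list alone and 0 over all genes tested. With each cell thinned to 1000 UMIs the difference in list level was 0.16, against 0.30 before. By label Trp53_KO replicate 2 held only 128 T cells, against 534 cells in its T cell clusters. Usp18, a protease that removes Isg15 from proteins, stood at 10.7 ± 1.88 against 1.46 ± 1.78 CPM (adjusted p = 0.113). Interferon gamma genes were positive in 17 of 22 members (median 0.33, adjusted p = 0.00239; adjusted p = 0.614 with an estimated correlation), a call lost without Trp53_KO replicate 3 (0.0700) and without Trp53_WT replicate 1 (0.105). Genes of exhausted T cells did not pass (adjusted p = 0.567): their median was -0.18 with 3 of 9 positive, while the test pointed up. With classes from clusters that list passed upward (median 0.37, adjusted p = 0.00878; adjusted p = 0.600 with an estimated correlation). Pdcd1, the checkpoint receptor PD-1, had a log2 fold change of -0.18 (SE 0.52), and it was 0.30 without Trp53_KO replicate 3. Tcf7, a transcription factor of naive and memory T cells, stood at 332 ± 70.2 against 351 ± 48.8 CPM. The cytotoxic (adjusted p = 0.834), naive and memory (0.344) and regulatory (0.348) lists did not pass either, and Lag3, Gzmb, Ifng and Foxp3 were too low to test.

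RNA of other cells moved with the groups in T cells. The haemoglobin genes Hba-a1 and Hba-a2, near-identical copies, fell from 76.2 ± 15.3 to 0.521 ± 0.481 CPM (adjusted p = 2.63e-10) and from 52.8 ± 17.3 to 0.316 ± 0.547 CPM (adjusted p = 2.34e-06). All 5 erythroid genes were negative, each fallen adjusted over the list alone and 2 over all genes tested (adjusted p = 5.77e-19; adjusted p = 0.258 with an estimated correlation). Neutrophil genes were negative in 6 of 7 members (median -3.21, adjusted p = 8.82e-09; adjusted p = 0.607 with an estimated correlation), with S100a8 at 39.7 ± 15.7 against 515 ± 574 CPM. The remaining gene that fell, Igfbp6, a binder of insulin-like growth factors, was chosen after its values were seen and stood at 1.11 ± 0.595 against 9.63 ± 3.73 CPM (adjusted p = 0.0326). In all, edgeR called 3 of 8101 genes, with 312 at an unadjusted p under 0.05, and DESeq2 called 7. The count was 2, 6 and 2 without Trp53_KO replicates 1, 2 and 3, and 7, 9 and 12 without Trp53_WT replicates 1, 2 and 3. The groups did not overlap for 9.23% of genes, where chance gives 10%.

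B cells of the Trp53_KO mice had type I interferon genes higher in 39 of 42 members (median 0.56, adjusted p = 2.03e-12; adjusted p = 0.614 with an estimated correlation), and 7 rose adjusted over the list alone against 0 over all genes tested. With each cell thinned to 1000 UMIs the difference in list level was 0.25, against 0.67 before. By label Trp53_KO replicate 2 held only 60 B cells, against 333 cells in its B cell clusters. Ifi27l2a, an interferon-induced mitochondrial protein, stood at 351 ± 96.6 against 71.1 ± 41.2 CPM (log2 fold change 2.30, SE 0.42), and DESeq2 called it (adjusted p = 2.09e-06) while edgeR did not (adjusted p = 1.00). Genes of the naive and memory T cell list were positive in 12 of 16 members (median 0.41, adjusted p = 0.00239; adjusted p = 0.632 with an estimated correlation), a call lost without Trp53_WT replicate 2 (0.151). Among them Bcl2, which protects lymphocytes from cell death, stood at 216 ± 17.5 against 155 ± 12.4 CPM. Interferon gamma genes (15 of 19 positive, adjusted p = 0.0193; adjusted p = 0.632 with an estimated correlation) gave 0.179 and 0.263 without Trp53_KO replicates 1 and 3 and 0.105 without Trp53_WT replicate 1. Neutrophil genes were negative in 10 of 11 members (median -1.86, adjusted p = 3.95e-05; adjusted p = 0.703 with an estimated correlation), with S100a8 at 109 ± 78.2 against 718 ± 665 CPM. By cluster, with a small cluster left out, 25.2, 26.6 and 16.5% of B cells held a UMI of S100a8, S100a9 or Retnlg in Trp53_KO. In Trp53_WT it was 97.8, 41.3 and 59.8%. RNA of neutrophils in the droplets was not separated from a change in B cells. All 6 erythroid genes were negative (adjusted p = 3.24e-05; adjusted p = 0.614 with an estimated correlation), though Hba-a1 was higher in Trp53_KO replicate 1 (516 CPM) than in Trp53_WT replicate 2 (175 CPM). With pruned labels Hba-a2, Hba-a1 and Hbb-bs turned positive, at log2 fold changes of 0.40, 0.46 and 0.78. By edgeR 0 of 8454 genes passed, with 327 at an unadjusted p under 0.05, and DESeq2 called 1. The count was 1 without Trp53_WT replicate 1 and 1 without Trp53_WT replicate 2. The groups did not overlap for 9.65% of genes, where chance gives 10%.

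Of the 25 lists, 14 passed in at least 1 class by label with the preset correlation and 11 in none. Those 11 held the p53 target list, whose adjusted p ran from 0.333 in T cells to 0.834, and the checkpoint ligand list, which had the lowest of these values (0.0801, in neutrophils) and passed there by fry (adjusted p = 0.0192). With classes from clusters 4 of the 11 passed, none of them with an estimated correlation. These were resident macrophage genes in neutrophils (up, adjusted p = 0.0159), T cell exhaustion in T cells, and cytotoxic genes (0.0368) and hypoxia and glycolysis (0.0388) in B cells, both down. With an estimated correlation 0 of the 35 calls held, and the lowest adjusted p was 0.258. Calls on lists that share members, such as type I interferon and nucleic acid sensing, are not separate results. On simulated counts with 1 changed list, the preset correlation also gave calls on 2 unchanged lists in macrophages and monocytes and 2 in B cells. Calls on the interferon gamma and sensing lists were not counted there. Genes were drawn independently in these counts, so they cannot show how many such calls arise where genes of a list vary together. With all cells of a mouse summed, edgeR called 0 of 12805 genes, with 1503 at an unadjusted p under 0.05, and DESeq2 called 392. The count was 32 without Trp53_WT replicate 2 and 1 without Trp53_KO replicate 2. The groups did not overlap for 17.7% of genes, where chance gives 10%.

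Neutrophils made up a smaller share of the sorted cells in Trp53_KO mice, 8.30, 3.0 and 4.10% against 57.7, 8.59 and 47.7% in Trp53_WT. The means were 5.13 ± 2.80% and 38.0 ± 25.9%, a log2 fold change of -2.89 (SE 0.92, edgeR adjusted p = 0.0291, exact permutation p = 0.1). By cluster the neutrophil shares were 9.96, 11.9 and 5.06% in Trp53_KO against 56.0% and 47.3% in Trp53_WT replicates 1 and 3, and Trp53_WT replicate 2 lay below Trp53_KO replicate 2, so the groups overlapped. Macrophages and monocytes made up 53.3 ± 29.0% against 29.6 ± 20.0% (adjusted p = 0.667), T cells 17.8 ± 12.6% against 14.3 ± 5.83% (0.956) and B cells 20.0 ± 16.7% against 14.6 ± 4.10% (0.956). Epithelial or stromal cells made up 0.620 ± 0.314% against 0.205 ± 0.266% (0.267). The adjusted p for neutrophils was 0.0737, 0.0544 and 0.106 without Trp53_KO replicates 1 to 3, 0.194, 0.00716 and 0.111 without Trp53_WT replicates 1 to 3, and 0.0512 with classes from clusters. In 100 simulations with 1 lowered class and a preset spread between mice, the same test made 10 calls on unchanged classes. That spread was not taken from the data, so the count need not hold here. All shares follow a live and CD45 sort whose gate the labels do not describe. Within T cells the gamma delta label made up 3.79 ± 3.0% against 6.49 ± 2.07% (log2 fold change -1.43, adjusted p = 0.0807).

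In Trp53_KO replicate 2 the labels and the clusters disagreed. Macrophage or monocyte labels stood on 72.8% of the cells in its T cell clusters, 80.8% in its B cell clusters and 74.4% in its neutrophil clusters. The next highest library, Trp53_WT replicate 2, had 19.7, 12.5 and 18.7%. Macrophages and monocytes made up 86.6% of the cells of Trp53_KO replicate 2 by label and 59.9% by cluster. The tests of genes by label thus used 128 T cells, 60 B cells and 119 neutrophils from this library, against 534, 333 and 472 cells by cluster. Its labelled T and B cells were also deeper, with median UMIs of 5064 and 4494.5. In the other libraries these medians reached at most 3384 and 2475, both in Trp53_KO replicate 3.

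**Figure D2:**
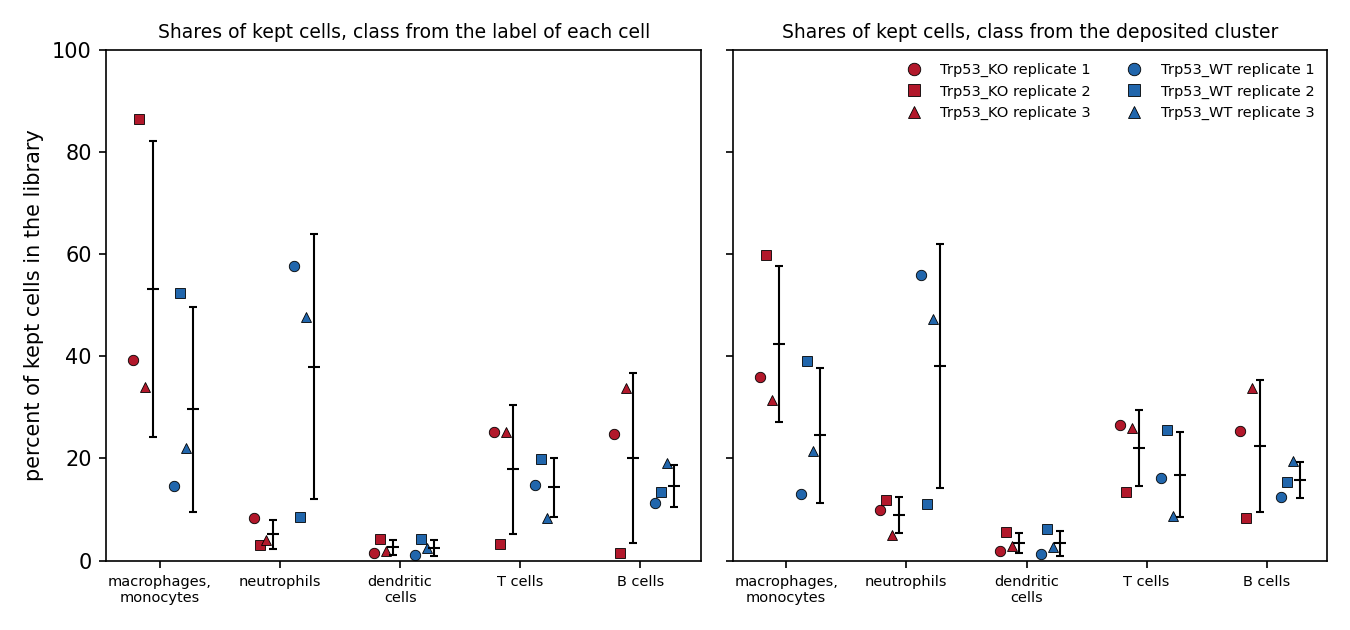
Share of each cell class in percent of kept cells per mouse, by label on the left and by cluster on the right, with points for replicates and bars for the mean ± SD of 3 mice. By label, neutrophils lay at 8.30, 3.0 and 4.10% in Trp53_KO and at 57.7, 8.59 and 47.7% in Trp53_WT.

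**Figure D3:**
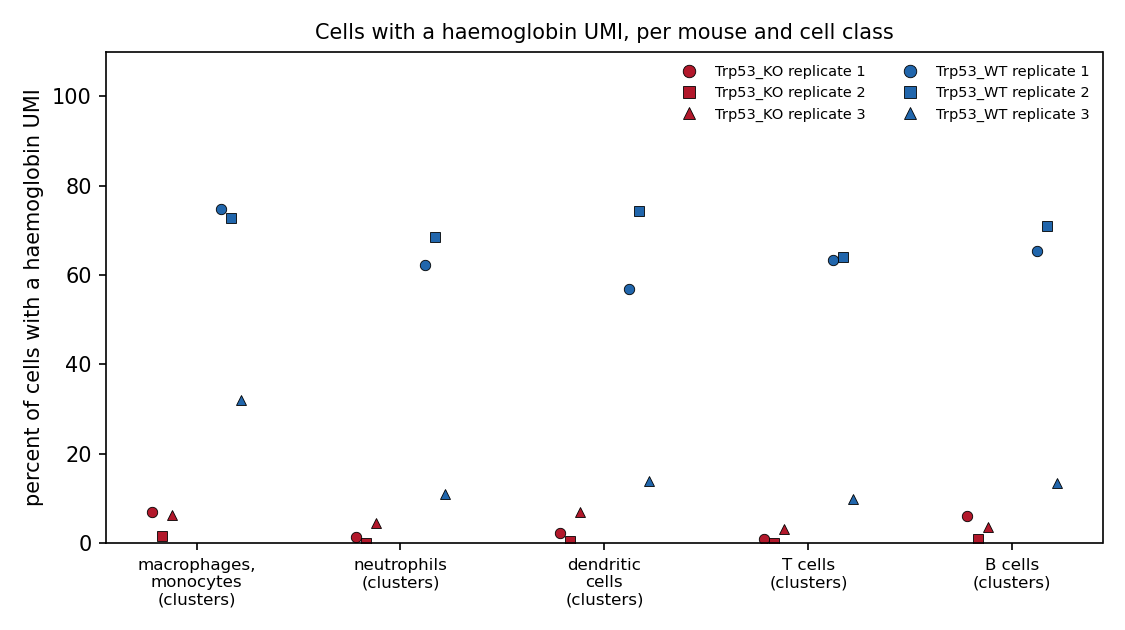
Percent of cells with at least 1 haemoglobin UMI in each mouse, by class from clusters. T cells of the Trp53_WT mice lay at 63.3, 64.1 and 9.82% and those of the Trp53_KO mice at 3.15% or less.

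Whether a change differed between macrophages and T cells was tested within each mouse. By limma 0 of 7919 genes passed, with 415 at an unadjusted p under 0.05, and no other tool was run on this difference. By camera 6 lists differed, 4 did with classes from clusters, and 10 did without Trp53_WT replicate 3. The type I interferon change was larger in macrophages and monocytes by a median of 0.62 on the log2 scale (adjusted p = 4.96e-15; adjusted p = 0.552 with an estimated correlation). The MHC class I change was larger by 0.52 (adjusted p = 5.73e-11; adjusted p = 0.310 with an estimated correlation).

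The deposited marker tables describe differences between clusters or cell sets and hold no comparison of the genotypes. Of 7865 matched genes in 13 distinct comparisons, 7624 (96.9%) had the same direction in counts summed per library, and 6049 also passed the threshold. The share ran from 91.2 to 100% between comparisons. The cells are the same in both, so this is not independent evidence.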

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

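All tests of explanations here were chosen after the result was seen, except the test of depth in macrophages and monocytes, whose bound was written before. The tests of the difference between classes were planned.

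The change between the groups differed between macrophages and monocytes and T cells for 6 lists, each tested on the difference within mice, and for 4 with classes from clusters. The median log2 difference was 0.62 for type I interferon (adjusted p = 4.96e-15; adjusted p = 0.552 with an estimated correlation) and 0.44 for interferon gamma (adjusted p = 2.44e-05; adjusted p = 0.552 with an estimated correlation). It was 0.52 for MHC class I (adjusted p = 5.73e-11; adjusted p = 0.310 with an estimated correlation). It was 1.92 for neutrophil genes (adjusted p = 0.00260; adjusted p = 0.705 with an estimated correlation) and -0.13 for oxidative phosphorylation (adjusted p = 0.00396; adjusted p = 0.705 with an estimated correlation). For erythroid genes it was -2.07 (adjusted p = 0.0421; adjusted p = 0.705 with an estimated correlation). With classes from clusters the calls on neutrophil genes (median 0.38, adjusted p = 0.174) and erythroid genes (median 0.41, adjusted p = 0.778) were lost. In Trp53_KO replicate 2 macrophage or monocyte labels stood on most cells of the T cell clusters and on 74.4% of those in the neutrophil clusters. Within macrophages and monocytes the neutrophil list fell by cluster and did not pass by label, so its difference between classes depended on these labels. Without Trp53_KO replicate 2 the calls on neutrophil genes, erythroid genes and oxidative phosphorylation were lost too (adjusted p = 0.0662, 0.523 and 0.0762).

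The type I interferon list was called higher in Trp53_KO mice in all 5 tested classes with the preset correlation and in none with an estimated one, where adjusted p ran from 0.607 to 0.736. A shift between macrophage subtypes is argued against by the group means. The Trp53_KO mean of the list was higher within each of the 6 clusters with mostly macrophage labels and at least 20 cells in every library (1 more was not tested). The median difference was 1.18 on the log2 scale. In some of these clusters the mice overlapped, with Trp53_KO replicate 2 below Trp53_WT replicate 3 (4.04 against 4.17 in the largest). Leading genes of 1 cluster included Ppbp and Pf4 and those of another Elane and Mpo, known from other cells. A greater weight of cells with many UMIs in the sums is argued against in macrophages and monocytes. There the difference was 1.33 after each cell was thinned to 1000 UMIs and 1.19 before. It is also argued against in neutrophils (1.21 after, 1.11 before). In neutrophils the floor of the bound was set after the values were seen, and an earlier floor, from the smallest library, had left depth undecided. Thinning leaves the expected CPM of each cell unchanged, so it could not test other effects of depth in any class. The weight of such cells stays open in dendritic cells (0.67 after, 0.74 before), T cells (0.16 after, 0.30 before) and B cells (0.25 after, 0.67 before). In these classes thinned levels of a library lay less than 1 log2 unit above that of 1 UMI. Free macrophage RNA stays open as well, since the excess in T cells lay 0.55 and that in B cells 1.24 standard errors above what such RNA would carry. Such RNA was not tested in neutrophils or dendritic cells. The genotype of the injected cells may underlie the pattern but stays open too, since all Trp53_KO mice lay above all Trp53_WT mice in 2 of the 5 classes and 3 against 3 mice cannot reach an exact p under 0.1.

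Haemoglobin RNA was lower in Trp53_KO mice across classes, except in B cells with pruned labels, where Hba-a2, Hba-a1 and Hbb-bs stood at 0.40, 0.46 and 0.78 on the log2 scale. Free red cell RNA in the droplets of Trp53_WT replicates 1 and 2 is a candidate explanation, since the share of cells with a haemoglobin UMI differed between classes by a ratio of at most 1.31 in these libraries. Red cells or their doublets among T cells are argued against in these libraries, where the 1% of T cells with the most haemoglobin UMIs held at most 5.10%. In Trp53_WT replicate 3 that 1% of T cells held 79.2%, so such cells stay open there. Among macrophages and monocytes such cells are a candidate explanation, since the top 1% held at least 81.9% in Trp53_WT replicates 1 and 2. No biological explanation of this pattern was tested, and red cells had been lysed before the sort.

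Macrophage labels on cells of the T and B cell clusters in Trp53_KO replicate 2 were weighed against 2 technical explanations, and both stay open. Macrophage marker CPM in these clusters was at most 0.846 times that of Trp53_WT replicate 2, where fewer cells carried such a label. Within Trp53_KO replicate 2, however, cells with that label held 1.88 times the macrophage marker CPM of T-labelled cells and 1.72 times that of B-labelled cells. Median UMIs of such cells in the T cell clusters were 1.02 times those of T-labelled cells elsewhere, but 0.563 times those of the T-labelled cells, and in the B cell clusters 0.473 times those of the B-labelled cells, of the same library. The source of the labels was not found, and no biological explanation was tested.

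Other splits of the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. In neutrophils the real split gave 5 genes and the highest other 0, so that 1 split gave as many. In T cells the real split gave 3 and the highest other 7, with 4 splits giving as many. In macrophages and monocytes (0 and 0), dendritic cells (0 and 1), B cells (0 and 3), all cells (0 and 0) and the difference between macrophages and T cells (0 and 0), 10 splits gave at least as many.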

How the results depend on the processing

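The removal of cells with top doublet scores, the restriction to pruned labels and the lists by cluster were chosen after the data were seen. Of 173 named genes 158 kept their sign under every alternative run, and 22 of the 35 calls of lists held without each library in turn, where they could be tested. Where a value below differs from the one reported, the cause was not tested. Changed genes by DESeq2 numbered 131 in macrophages and monocytes, 54 in neutrophils, 13 in dendritic cells, 7 in T cells, 1 in B cells and 392 in all cells. With no count filter they numbered 151 in neutrophils, 121 in dendritic cells, 44 in T cells and 5 in B cells. In neutrophils the count was 8 with RLE size factors, 9 with total counts only, 57 with classes by cluster, 2 with thinned counts and 8 without top doublet scores. In dendritic cells it was 2 with classes by cluster, 3 with thinned counts and 4 with at least 50 cells. In T cells it was 8 with total counts only, 0 with the cell filter and 5 with pruned labels. With total counts only the median log2 fold change of all genes stood at -0.149 in neutrophils and -0.120 in T cells. The replicate block, a pairing by replicate number that no label supports, gave 85 genes in neutrophils, 1 in dendritic cells, 23 in T cells and 6 in B cells. The deviations of mice with the same number correlated at 0.27, 0.31 and 0.11 in macrophages and monocytes, where each mouse correlated best with its own number. In neutrophils and B cells this held for all mice but Trp53_WT replicate 3, and in T cells and dendritic cells for fewer. The deposited data number the third Trp53_WT mouse 4, so the third pair of the block is doubtful. With the block the log2 share of B cells was -0.19 and that of neutrophils -2.63 (edgeR adjusted p = 0.0840). The share of gamma delta T cells was -1.14 (edgeR adjusted p = 0.0442) and that of the monocyte label -1.36 (edgeR adjusted p = 0.000802). Both of these passed the threshold with the block and not without it. Nos2 in macrophages and monocytes was 0.93 and Pdcd1 in T cells 0.19 with the block. The block lost no call of a list, and it added proliferation (adjusted p = 0.00421) and hypoxia and glycolysis (adjusted p = 0.00701) in macrophages and monocytes, 1 list in neutrophils and 2 in dendritic cells. Of the added lists, hypoxia and glycolysis, the resident macrophage list in neutrophils (adjusted p = 0.0357) and the T cell exhaustion list in dendritic cells (adjusted p = 0.0287) had passed in no class. Lists past the threshold numbered 0 in each of the 5 classes with an estimated correlation, and with fry 0 in macrophages and monocytes, 2 in neutrophils, 1 in dendritic cells, 1 in T cells and 0 in B cells. With classes from clusters 28 of the 35 calls of lists held, 6 were lost and 1 could not be tested, and 9 more were made, none of them with an estimated correlation. Among these were proliferation in macrophages and monocytes (down, adjusted p = 0.00773), interferon gamma in neutrophils (0.0221), lipid and complement macrophage genes in dendritic cells (0.000395) and nucleic acid sensing in T cells (0.0117). With the cell filter the neutrophil list in macrophages and monocytes passed (down, 0.0447), and the erythroid list could not be tested in neutrophils and T cells. With the cell filter the share of neutrophils was -2.90, that of dendritic cells -0.11 and that of the microglia label 2.91. With classes by cluster the share of neutrophils was -2.09 and that of the microglia label 2.95, and the neutrophil list in neutrophils pointed down (adjusted p = 0.252). By cluster Klf2 and Ly6c2 in neutrophils were -0.019 and -0.0018, Pdcd1 in T cells 0.93 and B2m in B cells -0.0049. B2m in B cells was -0.024 without top doublet scores, B2m in T cells -0.0039 with total counts only, Cd274 in dendritic cells 0.23 with at least 50 cells, and Pdcd1 in T cells 0.094 by DESeq2. With pruned labels Hba-a2, Hba-a1 and Hbb-bs in B cells were 0.40, 0.46 and 0.78. Of the authors' genes with an absolute log fold change of at least 0.5, 99.7% had the same direction. Leaving out each library in turn gave 0 to 8 genes in macrophages and monocytes, 0 to 13 in neutrophils, 0 to 5 in dendritic cells, 2 to 12 in T cells, 0 to 1 in B cells and 0 to 32 in all cells. Lists ran from 8 to 14 in macrophages and monocytes, 7 to 16 in neutrophils, 3 to 10 in T cells, 4 to 9 in B cells and 6 to 10 for the difference between classes. Log2 shares ran from -0.15 to 1.00 for B cells, -0.11 to 0.70 for NK cells, -0.018 to 0.81 for T cells and -0.54 to 0.60 for dendritic cells. They ran from 1.04 to 3.54 for epithelial or stromal cells, -3.42 to -2.45 for neutrophils and -0.98 to 0.82 for the microglia label. In macrophages and monocytes Cdkn1a ran from -0.12 to 0.70, Arg1 from -0.86 to 0.041, H2-Ab1 from -0.13 to 0.90 and Nos2 from -1.24 to 4.54. Cd274 in dendritic cells ran from -0.34 to 0.23, Isg15 in T cells from -0.10 to 0.74, Pdcd1 from -0.56 to 0.30, Tcf7 from -0.23 to 0.059 and B2m in B cells from -0.14 to 0.54. The RLE alternative for Trp53 was not run, since its class was not fitted, and macrophages could not be set against epithelial cells, which were too few. Fewer UMIs left fewer genes to test, in neutrophils 3100 with thinned counts against 5400.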

Other observations

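The shares of single clusters within a class were an alternative chosen after the data were seen. Within neutrophils, the cluster whose leading genes included Retnlg, Stfa2l1, S100a8 and Ngp, all known from neutrophils, made up 34.3 ± 3.50% in Trp53_KO against 20.6 ± 7.67% in Trp53_WT (SD, n = 3 mice each; log2 fold change 0.78, edgeR adjusted p = 0.0327). Its adjusted p was 0.0761, 0.145 and 0.0732 without Trp53_KO replicates 1 to 3, and 0.136, 0.000304 and 0.174 without Trp53_WT replicates 1 to 3. Within B cells, a cluster with few UMIs per cell (0.442 times the library median) made up 11.5 ± 3.54% against 27.2 ± 7.05% (edgeR adjusted p = 0.0356). Its adjusted p was 0.0571, 0.0613 and 0.102 without Trp53_KO replicates 1 to 3, and 0.0959 without Trp53_WT replicate 1. Against the largest B cell cluster, the authors' tables gave this cluster S100a9, S100a8 and Chil3 as leading genes. S100a8 and S100a9 are neutrophil genes, and RNA of neutrophils in the droplets was not separated from a shift between B cell clusters.

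Between other pairs of classes limma called no gene whose change differed. It called 0 of 8308 genes for macrophages against B cells (359 at an unadjusted p under 0.05), 0 of 7563 for T cells against B cells (253) and 0 of 5371 for macrophages against neutrophils (414), and no other tool was run. By camera 9, 4 and 7 lists differed in these pairs, and none of them with an estimated correlation, where the lowest adjusted p was 0.213, 0.651 and 0.421.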
